A study of Mus musculus with 3 samples.

How the data were processed

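The study measured where the transcription factor PBX1 lies on chromatin in the ventral midbrain of wild-type C57BL/6 mouse embryos at embryonic day 12.5, by chromatin immunoprecipitation followed by sequencing (ChIP-seq). Per the labels, 1 library was made with an antibody against PBX1, 1 with a control IgG, and 1 from input, the chromatin set aside before precipitation (2% of it). Per the labels' protocols, the tissue was made into a single-cell suspension, precipitated with a commercial agarose kit, ligated to adapters, selected for size on a gel, amplified by PCR and selected again. The labels give the molecule as nuclear RNA and the library source as transcriptomic, which does not match the DNA work in the protocol; the data were treated as ChIP-seq.

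Reads were aligned with Bowtie to the mm9 mouse genome and peaks were called with HOMER, per the submitters' processing notes; the versions, the alignment settings and the handling of reads that fit several places are not given in the sources used here. Per the file headers, the authors ran HOMER's findPeaks in its transcription factor mode on each immunoprecipitated library, with the input library as control and a false discovery rate of 0.05. A candidate region had to hold at least 7 tags in the PBX1 library or 6 in the IgG library. It then had to reach a fold of 4 over input and a fold of 4 over the surrounding 10000 bp, each with a Poisson p-value of at most 0.0001, per the file headers. At most 1 tag per base pair was considered, and the genome size was set to 2000000000 bp. Nothing was pooled, as each list comes from 1 library.

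The deposited lists hold positions only: a name, chromosome, start and end for each peak, all 65 bp wide in the PBX1 list and all 57 bp wide in the IgG list. Tag counts, scores, folds and p-values of single peaks are not columns of these lists, so depth is known per library and not per peak. The PBX1 list also carries up to 2 gene symbols per peak, added by the authors; the rule that chose them is not given in the sources used here. Of 596 distinct symbols, 584 were matched to a symbol or unambiguous synonym of the RefSeq gene table of assembly GRCm38.p6, which was used for names and for the order of neighbouring genes, never for coordinates. They came to 579 of the 21900 protein-coding genes of that table. In 267 of the 324 rows with a pair of different coding genes on 1 chromosome, the pair were immediate neighbours among coding genes, so the symbols are called genes beside a peak here.

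From these files were computed the overlap of the lists (at least 1 bp), the distances between peak centres, runs of at least 3 PBX1 peaks spaced by at most 100 kb, and closely spaced peaks with centres within 1 kb. Exact 95% binomial (Clopper-Pearson) intervals were given for shares; a count of 0 was set against a floor of 3 peaks. Intervals and floors cover counting error only. The chance of peaks lying near each other was taken from 10000 random rotations of the IgG peaks inside the span that both lists cover on each chromosome. The distribution over chromosomes was compared by a permutation test with 100000 permutations of the list label. Both took the place of planned comparisons with full chromosome lengths, which were not used here, and were chosen after the lists had been seen. The 12 gene lists had been written down before the data were examined; each was tested with a two-sided Fisher's exact test of its members among genes beside PBX1 peaks, against all protein-coding genes, with Benjamini-Hochberg adjustment over the 12 lists. A count of list members was also set against 10000 draws of 313 random pairs of neighbouring coding genes, the number of distinct gene pairs beside peaks. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

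The steps were tested on simulated data. With 579 random genes, the Wnt list was called in 0% of 200 simulations, and any other list in 1%; with 6 members added, the Wnt list was called in 100% of them. With 30 PBX1 peaks moved beside displaced IgG peaks, the permutation test with 2000 rotations gave p = 0.0005. With none moved the permutation test gave p = 0.562. The simulated genes were drawn singly and not as neighbouring pairs, and the Wnt list had 3 members beside peaks in the data, not 6. The displaced IgG peaks were spread at random, and each setting was run once. The simulations therefore do not give error rates for paired genes or clustered peaks, or the power at the counts seen.

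With 1 library per antibody there is no replicate error, and each test compares 2 lists from single libraries, or genes within 1 list, not conditions. Also before the data were examined, a rule was set for the genes to name: the 25 best-ranked PBX1 peaks, every peak beside a gene of a fixed list, every PBX1 peak that overlaps an IgG peak, and the 5 best-ranked IgG peaks. The lists carry no column of score or rank, and the order of their rows was not used as a rank. The first and the last part were therefore not applied, and the third part found no peak. Genes beside closely spaced peaks and in runs are named under a rule added after the lists were seen. Planned work on tag counts per peak, on promoter and other locations and on sequence motifs was not done, because it needs columns, an mm9 annotation or an mm9 sequence that were not used here. The alternatives tried were merging of nearby peaks, leaving out chromosome Y, other definitions of overlap, either gene column alone, another gene background, leaving out rows with misplaced symbols, leaving out peaks near IgG peaks, and random gene pairs.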

Results

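The data consist of 2 lists of peaks from the ventral midbrain of mid-gestation mouse embryos, the region in which midbrain dopaminergic neurons form. PBX1 is a homeodomain transcription factor of the TALE class. The question was which genomic sites and which genes it occupies in this tissue. One list came from the PBX1 library and the other from the control IgG library, each called against the same input library. The PBX1 library held 12767287.5 tags and the IgG library 12758345.5 tags, a ratio of 1.00. There was 1 library per antibody, so no difference below has a replicate check.

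The PBX1 antibody gave 386 peaks and the control IgG gave 69, so the PBX1 list was 5.59 times as long at nearly equal total tags. A candidate region needed 7 tags in the PBX1 library and 6 in the IgG library, so the lists were not called at the same threshold. The peaks lay on every autosome and on both sex chromosomes in the PBX1 list. PBX1 peaks held 4879.7 tags of the PBX1 library (0.0382%), and IgG peaks held 603.2 tags of the IgG library (0.00473%). A PBX1 peak held a mean of 12.6 tags and an IgG peak a mean of 8.74 tags. These means were 32.6 and 27.1 times the number that the peak caller expected for a stretch of that size.

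The libraries differed in the number of candidate regions and in the share that each filter removed. Before filtering, the IgG library had 1964 candidates and the PBX1 library 1680, at their different thresholds. Comparison with input removed 1865 IgG candidates (94.96%, 95% Clopper-Pearson interval 93.9 to 95.9%) and 1200 PBX1 candidates (71.4%, interval 69.2 to 73.6%). The filter on local signal then removed 30 of the 99 remaining IgG candidates (30.3%, interval 21.5 to 40.4%) and 94 of the 480 remaining PBX1 candidates (19.6%, interval 16.1 to 23.4%). In all, 23.0% of PBX1 candidates (interval 21.0 to 25.1%) and 3.51% of IgG candidates (interval 2.74 to 4.43%) became peaks. The intervals cover counting error within each library and not the variation between embryos or precipitations.

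**Figure D1:**
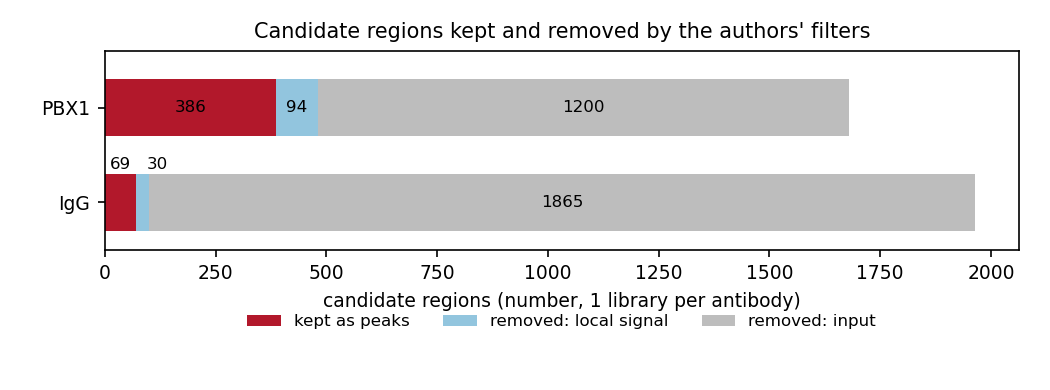
Number of candidate regions in the PBX1 and the IgG library (x axis, 1 library each), divided into those kept as peaks and those removed by the authors' filters on local signal and on input. The kept part is 386 of 1680 regions for PBX1 and 69 of 1964 for IgG.

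Of the genes in the 12 fixed lists, 12 had a PBX1 peak beside them, at 16 peaks. Pitx3, a homeobox gene required by dopaminergic neurons of the substantia nigra, had a PBX1 peak at chromosome 19:46226796-46226860 (mm9), where the authors also named Gbf1. Onecut2, a cut-homeobox transcription factor gene, had a peak at chromosome 18:64499587-64499651 (St8sia3 on the other side). Nfe2l1, a bZIP transcription factor gene of the stress response, was named with Copz2 at chromosome 11:96691341-96691405. These 3 genes were known beforehand as genes that the study followed up. Of that list of 5 genes, 3 had a peak where 0.132 would be expected among 579 genes (two-sided Fisher's exact test, adjusted p = 0.00212 over the 12 lists). The list was chosen by the study on these samples, so its count is not independent evidence. With the first gene column alone 2 members were left and the call was kept (Fisher's exact test, adjusted p = 0.0226). With the second alone 1 member was left and the call was lost (Fisher's exact test, adjusted p = 0.261). The rule that gave genes to peaks is not stated, and a rule of nearest genes would favour genes in large intergenic regions. Onecut1 and Onecut3, its other members, had no peak.

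Among Wnt pathway genes, 3 of 27 had a PBX1 peak beside them, against 0.714 expected. Wnt5a, which encodes a secreted Wnt ligand, was named for 2 peaks on chromosome 14, at 28436725-28436789 and at 29771972-29772036, 1.34 Mb apart. Lrp5, a Wnt co-receptor gene, was named with Ppp6r3 for 2 peaks spaced by 141 bp on chromosome 19, at 3575877-3575941 and 3576018-3576082. Fzd1, a Frizzled receptor gene, shared a peak with Cdk14 at chromosome 5:5342917-5342981. The excess of Wnt genes did not pass the threshold after adjustment (Fisher's exact test, adjusted p = 0.134).

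Among 17 oxidative stress genes, 3 had a PBX1 peak against 0.449 expected, which did not pass the threshold either (Fisher's exact test, adjusted p = 0.0569). They were Nfe2l1 again, Hmox1, the gene of the inducible heme oxygenase, at chromosome 8:77557916-77557980, and Sod1, the gene of cytosolic superoxide dismutase, at chromosome 16:90144467-90144531. Nfe2l1 is also on the list that the study chose on these samples, so this count is not fully independent evidence. Pknox2, another TALE homeobox gene, was the only 1 of 21 genes in the list of TALE genes and partners with a peak (adjusted p = 0.891 by Fisher's exact test). It had 2, at chromosome 9:36954816-36954880 and 37015670-37015734. Among 20 regulators of chromatin and transcription in neurogenesis, 2 had a peak (adjusted p = 0.291 by Fisher's exact test). Ezh2, which encodes the histone methyltransferase of Polycomb complex 2, was named at chromosome 6:47596949-47597013. Nfia, a nuclear factor I gene, was named for 2 peaks on chromosome 4, at 97316144-97316208 and 97440025-97440089.

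Pitx3 was the only 1 of 30 measured midbrain dopaminergic and floor-plate transcription factor genes with a PBX1 peak (Fisher's exact test, adjusted p = 0.940), and none of the other 29, such as Lmx1a, Lmx1b, Foxa2, Nr4a2 and En1, was named in the list. The lists of dopaminergic transmitter genes (11 genes, with Th, Ddc and Slc6a3), neural progenitor and Notch genes (17), Shh and Fgf pathway genes (16), axon guidance and adhesion genes (38) and markers of other neurons of the region (20) had 0 members beside a peak. With 0.291 to 1.00 members expected, a count of 0 in these 5 lists is within chance, with adjusted p between 0.940 and 1.0 in Fisher's exact test. Of 22 markers of blood, vessel, mesenchyme and microglia, only Foxc1, a forkhead gene of mesenchyme, had a peak (with Gmds, chromosome 13:32402103-32402167, adjusted p = 0.891 by Fisher's exact test). The 16 peaks beside the 12 genes of all lists lay at least 3.18 Mb from the nearest IgG peak. Such distance was usual: of all PBX1 peaks outside runs, only 3 of 329 had an IgG peak within 100 kb. It is therefore not evidence that these peaks are specific. Whether a peak lies in an exon, an intron, a UTR or between genes was not determined here.

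Closely spaced PBX1 peaks marked 23 sites, with 46 of the 386 peaks (11.9%). At each site the centres of 2 peaks were within 1 kb, and the median spacing was 262 bp (range 128 to 746 bp). The IgG list held no such site, but it had only 69 peaks. The difference was not tested, so the count of 0 does not show that such sites are particular to PBX1. Whether the 2 PBX1 peaks of a site mark separate places or 1 enriched region called as 2 peaks was not tested either. Besides Lrp5, the genes named at these sites included Sp2 and Sp6 (chromosome 11:96839137-96839403), genes of zinc-finger factors of the Sp family. They also included Zbtb20 with Gap43, the gene of a growth-cone protein (chromosome 16:42875677-42875935), and Cic, the gene of the transcriptional repressor capicua, with Pafah1b3 (chromosome 7:26053167-26053411). Hbp1, the gene of an HMG-box repressor, was named with Gpr22 (chromosome 12:32635103-32635325), and Prmt1, the gene of an arginine methyltransferase, with Bcl2l12 (chromosome 7:52241795-52242289). Others lay beside Josd1 and Gtpbp1 (chromosome 15:79520816-79521028), Ankhd1 and Slc4a9 (chromosome 18:36719947-36720201), Agpat1 and Rnf5 (chromosome 17:34740587-34740840), Rpia and Eif2ak3 (chromosome 6:70794168-70794516), and Osbp and Patl1 (chromosome 19:12039758-12040091). Of the 23 sites, 1 lay within 100 kb of an IgG peak, beside 4932411N23Rik on chromosome X.

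No PBX1 peak overlapped an IgG peak. The count was 0 of 386, which allows a share of up to 0.777%. Within 100 kb, however, 33 PBX1 peaks (8.55%, Clopper-Pearson interval 5.96 to 11.8%) had an IgG peak, against a mean of 2.42 and a maximum of 18 in 10000 random rotations of the IgG peaks (one-sided permutation p = 0.0001, the smallest these rotations can give). Within 10 kb there were 9 such peaks against a mean of 0.300 (one-sided permutation p = 0.0001). Of the 33, 30 stood in runs of PBX1 peaks. There were 13 runs of at least 3 PBX1 peaks, holding 57 peaks, and 5 of these runs had IgG peaks within 100 kb.

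The longest run held 11 PBX1 peaks and 4 IgG peaks on chromosome 8 between 19683835 and 20028403, beside 4930467E23Rik, Gm15319, 6820431F20Rik and the beta-defensin gene Defb7. The next held 8 PBX1 and 3 IgG peaks on chromosome 5 between 14933653 and 15212131, beside Speer4d, Speer4e and Cacna2d1. On chromosome X, a run of 5 and a run of 4 PBX1 peaks beside 4932411N23Rik each had 1 IgG peak. On chromosome Y, all 3 PBX1 peaks, beside Rbmy1a1, formed a run with 1 IgG peak. Together these 5 runs held 31 PBX1 peaks (8.03% of that list) and 10 IgG peaks (14.5%). Runs with no IgG peak within 100 kb lay beside 1600014C10Rik and Plekhf1 (5 peaks, chromosome 7:38962158-38985093), Zfp640 (3 peaks, chromosome 13:66526745-66535440) and Zfp960 (3 peaks, chromosome 17:17088417-17200953), among 8 such runs.

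**Figure D2:**
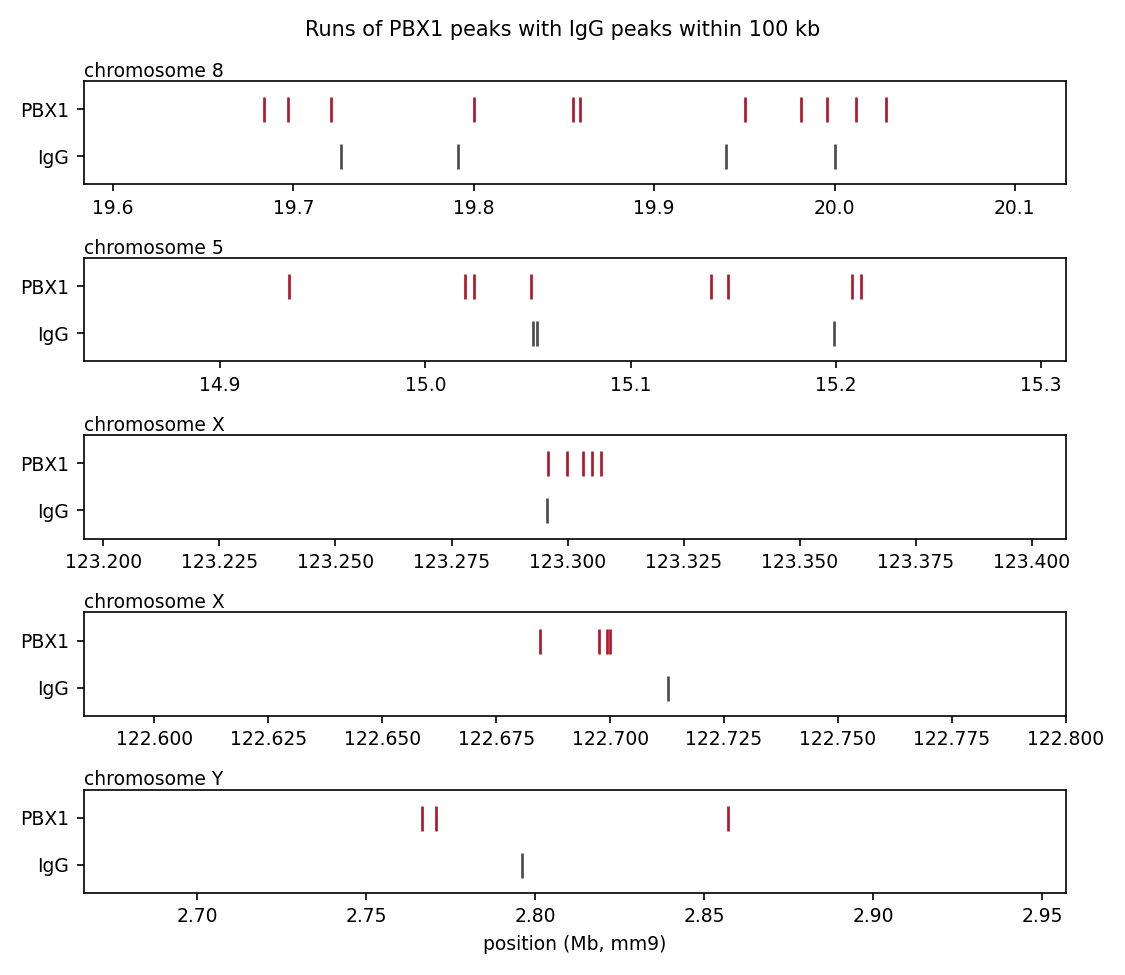
Positions (x axis, Mb, mm9) of PBX1 peaks (upper row, red) and IgG peaks (lower row, grey) in the 5 runs of at least 3 PBX1 peaks that had an IgG peak within 100 kb. Each mark is 1 peak, and the axes differ in scale. The run on chromosome 8 holds 11 PBX1 and 4 IgG peaks, interleaved without overlap.

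The lists also differed in their distribution over chromosomes (two-sided permutation test of the list label, 100000 permutations, p = 0.0131). Chromosome 7 held 44 PBX1 peaks (11.4%), the most of any chromosome, and 1 IgG peak (1.45%). Chromosomes 11 and 17 each held 27 PBX1 peaks (6.99%) and 1 IgG peak. Chromosome 16 held 9 PBX1 peaks (2.33%) and 6 IgG peaks (8.70%). Chromosome 15 held 14 PBX1 peaks and no IgG peak, and a count of 0 of 69 allows a share of up to 4.35%. Peaks in runs are not independent; with peaks within 100 kb merged, so that each run counted once, p was 0.0241 in the same permutation test.

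**Figure D3:**
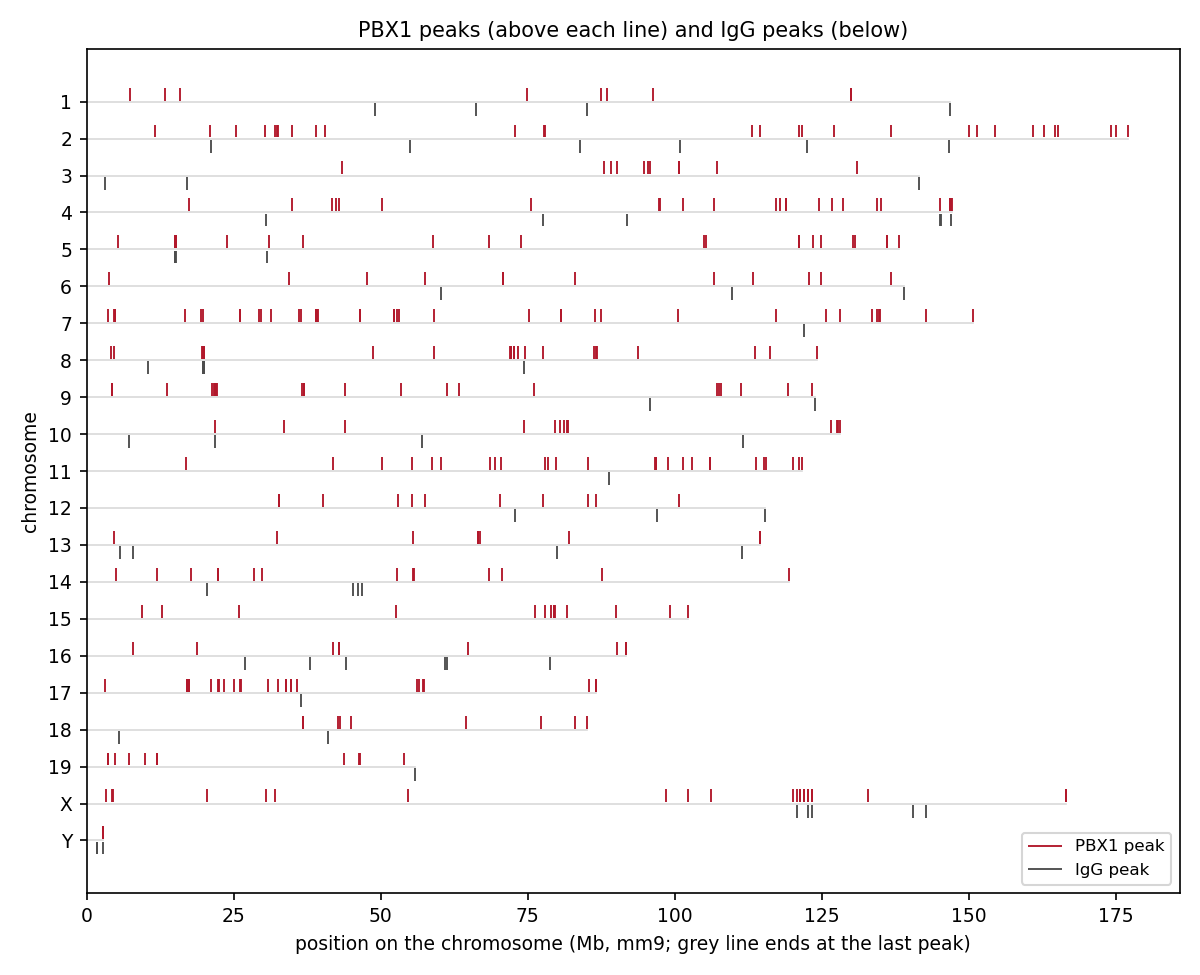
Positions of all 386 PBX1 peaks (red, above each line) and 69 IgG peaks (grey, below) along the mouse chromosomes (y axis) in Mb (x axis, mm9). Each mark is 1 peak, and groups of both kinds lie close together on chromosomes 5, 8 and X.

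The gene symbols of 6 PBX1 rows did not belong to the chromosome of their peak. They were the rows naming Scai with Ppp6c (peak on chromosome 12), Egln3 with Npas3 (chromosome 2), Tusc2 with Rassf1 (chromosome 11), Dcaf7 with Kcnh6 (chromosome 9), 1600014C10Rik with Plekhf1 (chromosome 5) and Speer4d with Gm17019 (chromosome 7). None of these genes is in a fixed list. In the runs on chromosomes 5 and 7 above, 1 row each carries such symbols.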

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

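The tests on runs of peaks, on misplaced gene symbols and on peak names were chosen after the results had been seen. The numbers in the peak names, a part of the lists not used in any comparison, ran far above the number of peaks on some chromosomes. On chromosome 8 the highest number in a PBX1 peak name was 412, against 174 in the IgG list, although only 30 PBX1 peaks were listed there. The highest numbers summed over chromosomes came to 1560 in the PBX1 list, which had 1680 candidate regions, and to 1804 in the IgG list, which had 1964. On chromosome 9 the lowest number among 22 PBX1 peaks was 62.

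The runs of PBX1 peaks on chromosomes 5, 8, X and Y were weighed first. Pile-up of reads in duplicated gene clusters, with any antibody, predicts IgG peaks beside them. With each run counted once, 5 of 13 (38.5%, exact interval 13.9 to 68.4%) lay within 100 kb of an IgG peak, against 3 of 298 groups of 1 or 2 peaks (1.01%, interval 0.208 to 2.91%; two-sided Fisher's exact test, p = 2.9e-06). Runs are not fully independent units: 4 of the 13 lay on chromosome X between 121267263 and 123307359. Of these, the runs beside 4932411N23Rik had an IgG peak within 100 kb. Those beside Vmn2r121 lay 483 and 697 kb from the nearest. The interval and Fisher's exact test treat such neighbouring runs as separate. Random rotations of the IgG peaks, which allow for the length of the runs, placed IgG peaks near a mean of 0.302 and at most 3 of the 13 runs (one-sided permutation p = 0.0001, the smallest the draws can give). Runs were defined from PBX1 peaks alone, but after both lists had been seen, so pile-up is a candidate explanation for the 5 runs and not shown by these tests. For the 8 runs without IgG peaks the question stays open: chance would place only a mean of 0.284 of their peaks near an IgG peak, and the 1865 IgG candidates removed by input have no listed position; binding of PBX1 there cannot be told apart from pile-up.

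The misplaced gene symbols were weighed next. Exchanging the symbols within 3 pairs of rows puts all 6 rows right: chromosome 2 with 12, chromosome 9 with 11, and chromosome 5 with 7. Each of the 6 rows has exactly 1 partner, consistent with an exchange of symbols between rows. Gene order showed 4 more rows out of sequence, 2 of them on chromosome 10: the rows naming Gm10778 with Ankrd24 at 21895625 and 4930444G20Rik with H60b at 81111693. No biological explanation was tested.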

How the results depend on the processing

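The alternatives on gene lists, the merging within 1 kb, the distances of 100 kb and leaving out PBX1 peaks near IgG peaks were chosen after the data had been seen. Merging peaks within 10 kb (345 PBX1, 67 IgG) or within 1 kb (363 and 69), leaving out chromosome Y (383 and 66), or leaving out PBX1 peaks within 100 kb of an IgG peak (353) kept both counts of peaks within 1.5 times of those reported. No PBX1 peak overlapped an IgG peak under either definition of overlap, but 1 had an IgG centre within 0.5 kb, 2 within 1 kb, 9 within 10 kb and 33 within 100 kb. With only the second gene column, the list of followed-up genes kept 1 member and lost its call (Fisher's exact test, adjusted p = 0.261), while the midbrain transcription factor list and the TALE list fell to 0 members, below expectation; fewer genes are tested there, and the cause was not tested further. With only the first gene column, the list of followed-up genes kept 2 members and its call (Fisher's exact test, adjusted p = 0.0226). The list of blood, vessel, mesenchyme and microglia markers fell to 0 there. With all genes of the reference as background, the Wnt list (3 members, adjusted p = 0.0151) and the oxidative stress list (3 members, adjusted p = 0.00573) passed the threshold in Fisher's exact test. That background adds genes that are not protein-coding. Against random neighbouring pairs of genes neither did (adjusted p = 0.338 and 0.184 from permutation draws), and the followed-up genes did (adjusted p = 0.012 from the same permutation draws). The followed-up genes, with Nfe2l1 of the oxidative stress list among them, were chosen on these samples. The counts of both lists are therefore not independent evidence. The chromosome test kept its call with peaks within 10 kb merged (permutation p = 0.0140) or within 100 kb (0.0241); leaving out overlapping peaks removed none, and leaving out peaks near the other list parts the lists by construction, so neither tests it. Of 107 results under alternatives, 93 kept their direction and their side of the threshold or stayed within the range allowed for a count. Another 4 moved, 3 reversed, 5 lost a call and 2 gained one. Of the 93, 3 were in the chromosome settings just named that test nothing. Others could not change either: the 5 lists with 0 members could not gain any. Leaving out misplaced rows or peaks near IgG peaks removed no list member. The tally is therefore not a measure of how stable the results are. Planned stricter thresholds on fold (8), p-value (1e-06), score or clonality, gene distances, and IgG genes as background were not run, because the lists lack these columns. No replicate could be left out, and no paired analysis was possible because each group has 1 library. What the depth limits is the single peak: with a mean of 12.6 tags in a PBX1 peak and a minimum of 7 tags, weaker sites could not be called.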

Other observations

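Families of gene symbols were examined after the lists had been seen, by testing all 102 symbol stems with at least 20 coding genes for an excess or a lack beside PBX1 peaks (two-sided Fisher's exact test, Benjamini-Hochberg adjustment). For the further tests on Zfp genes, what each explanation would show was set down before its result was known, but the count by place was added afterwards, and the reading of the comparison with IgG peaks was settled after its values were seen and had changed more than once. Zinc-finger genes named Zfp were in excess: 32 of 397 lay beside a PBX1 peak, against 10.5 expected, 3.05 times as many (adjusted p = 1.3e-06 in Fisher's exact test). Among them were Zfp809, which encodes a silencer of retroviral DNA, Zfp143, a promoter-binding activator, and the neighbours Zfp947 and Zfp944, as well as Zfp960, Zfp97, Zfp868 and Zfp938. Olfactory receptor genes were rare: 1 of 1110 (Olfr311) against 29.3 expected (adjusted p = 3.6e-10 in Fisher's exact test). Fisher's exact test counts neighbouring genes as independent. Against random neighbouring pairs the lack passed too (mean of 31.4 in the draws, adjusted p = 0.0102 from permutation draws). The p before adjustment, 0.0002 from these draws, is the smallest that 10000 two-sided draws can give. Its size can therefore not be set against that of Fisher's exact test. The Zfp excess stood at the same limit (32 against a mean of 11.3 and a maximum of 29, adjusted p = 0.0102 from permutation draws). Another stem, Btbd, had 6 genes of the Btbd35f group beside 5 peaks on chromosome X, against 1.11 expected (Fisher's exact test, adjusted p = 0.0264), but did not pass against random neighbouring pairs (adjusted p = 0.449) or with either gene column alone.

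Outside the fixed lists, PBX1 peaks were also named beside Nkx2-1 with Mbip (chromosome 12:57446900-57446964), Hand2 with Fbxo8 (chromosome 8:59030305-59030369), Suz12 with Utp6 (chromosome 11:79775862-79775926), Numb (chromosome 12:85263059-85263123) and Wnt10a with Cdk5r2 (chromosome 1:74901369-74901433). Nkx2-1 and Hand2 encode developmental transcription factors, Suz12 a Polycomb complex 2 subunit, Numb an inhibitor of Notch signalling and Wnt10a a Wnt ligand. These genes were chosen after their values were seen.

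The excess of Zfp genes might come from gene clusters in which 1 region names several genes. Counted as clusters of genes at most 5 places apart, 22 of 192 Zfp clusters had a peak beside them, against a mean of 8.75 and a maximum of 20 in 10000 draws of random neighbouring pairs (one-sided permutation p = 0.0001, the smallest the draws can give). Counting several genes of a cluster is therefore not the whole of it. Pile-up that is seen with IgG too stays open, because both outcomes set down beforehand were met. Of the 40 peaks beside Zfp genes, 6 of them in runs, 2 (5.0%) lay within 100 kb of an IgG peak. Of the other peaks outside runs, 1 of 295 did (0.339%, two-sided Fisher's exact test, p = 0.0386), fewer, as pile-up predicts. Peaks in runs were left out on that side only. Outside runs the Zfp share was 2 of 34 (5.88%). Among all 386 PBX1 peaks, however, 33 (8.55%) had an IgG peak within 100 kb, a larger share than the 5.0%. The direction of the comparison thus depends on leaving out runs. Yet the upper 95% limit of the share of 5.0% among the 40 Zfp peaks, 16.9%, is below the 50% set down as evidence against pile-up. That bound was wrong as an exclusion, because input removed 1865 of the 1964 IgG candidates and their positions are not listed, so a missing IgG peak does not show that reads did not pile up there with IgG. The p of 0.0386 rests on 1 place: both peaks lay near the same IgG peak on chromosome 4, and outside runs, with such peaks counted once, 1 of 28 Zfp places and 1 of 269 others had an IgG peak (Fisher's exact test, p = 0.180). These counts depend on the cutoff of 100 kb. Just past it lay Zfp peaks beside Zfp961 on chromosome 8 (100147 bp from an IgG peak) and Gm13051 on chromosome 4 (113031 bp). The next other peak outside runs lay 140619 bp away, and no other cutoff was tested. Without peaks near IgG peaks, 30 Zfp genes remained in excess (adjusted p = 1.2e-05 in Fisher's exact test). With the first gene column alone 23 were in excess (Fisher's exact test, adjusted p = 1.0e-06). With the second alone the 12 found did not pass (Fisher's exact test, adjusted p = 0.307). Binding of PBX1 beside Zfp genes remains a hypothesis.

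HOMER estimated fragment lengths of 64 bp in the PBX1 library and 56 bp in the IgG library. The density that the headers give for each library, multiplied by the genome size they use, comes to 93.4% of the tags in the PBX1 library and 88.6% in the IgG library.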
